A study of Drosophila melanogaster with 30 samples.

How the data were processed

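The series holds 30 Affymetrix fly arrays of total RNA from Kc cells, 3 for each of 10 groups. The design text names the control RNA and all knockdowns except E2F1, which only the sample titles name. Per the labels, cRNA labelled with biotin was made from 10 micrograms of total RNA after 4 days of RNAi. The deposited table gives 1 value per probe set and array, from 1.949 to 13.597, which were read as log2 signals from their range; the labels do not state the log base. The submitters' processing notes name GCOS 1.2.0. The normalization and summarization used by the authors are not stated. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples. For arrays, their number limits the precision.

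The comparisons, tests, filter, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Values were used as deposited, because on the log2 scale every array's 2% trimmed mean lay within 5% of the median array. On the linear scale the 3 L(3)MBT arrays lay 5.89 to 10.2% above it and all others from -2.03 to 3.23%, so quantile normalization is among the alternatives. Probe sets above their own array's median in at least 3 arrays were tested, 7794 of the 14010 probe sets after 44 control probe sets were left out. The deposited probe annotation paired 12443 probe sets with 1 gene each (10845 genes), 12393 of which had their gene ID in the reference table. A further 327 belonged to several genes and 1196 carried no name here, so they were counted but not named.

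Group means of all 30 arrays were fitted together in limma 3.58.1 (R 4.3.3; lmFit, eBayes with an intensity trend, 20 residual degrees of freedom). Two-sided p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. There were 9 contrasts with the control and 6 direct contrasts between knockdowns. Tables, permutations and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

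In the 9 contrasts with the control 21 gene lists were tested with limma's camera (preset correlation 0.01), with 1 probe set per gene and lists of at least 5 measured genes. They covered dREAM subunits, mitosis, centrosome, DNA replication, DNA damage and apoptosis, germ line and piRNA, meiosis and testis, neuronal, photoreceptor, muscle, hemocyte, fat body and gut, immune, ecdysone, patterning, Hippo, heat shock and stress, RNA interference, ribosomal protein, proteasome and oxidative phosphorylation genes. The 189 p-values were adjusted together; those of the direct contrasts were adjusted as their own family. Camera with an estimated correlation and fry were run beside it. The median and mean of every called list had the sign of its call.

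Genes were named by this rule: the RNAi targets; the 5 largest rises and 5 largest falls in each knockdown among called genes whose 3 knockdown values all lay on one side of the 3 control values and whose higher group mean was above 6.546, the median of all tested values; up to 3 called members of each list that was called or held at least 3 called genes; and the 3 largest differences each way in each direct contrast. Only probe sets with 1 gene were named, and each gene was read by its brightest probe set. For a list that was not called, the gene with the largest change stands for the list. The standard errors of the named changes ran from 0.0352 to 0.19. Of 387 pairs of gene and comparison named through a list, 379 (97.9%) had the 3 arrays of each group fully apart, which chance gives for 10%, and they were chosen among called genes. The probe sets of Ppn, achi, Act79B, Act87E, LysB, Hsc70-3 and CG8066 carry a suffix for probes shared between transcripts.

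Overlaps were set beside those of independent lists, and correlations beside 100 simulated draws of unchanged groups against the same 3 controls. The replicate numbers were checked as pairs in the 15 contrasts: every correlation passed 0.1 for Myb against control, and in 0 contrasts did every array correlate best with its own number, so pairing was not part of the model. The steps were tested on simulated data for the Mip40 contrast with 7794 probe sets: 96% of 100 genes changed by 0.5 and 100% of 100 genes changed by 1 were recovered, with 9 false calls (4.39% of calls). A simulated list shifted by 0.2 had an adjusted p of 2.42e-22, and 0 of 100 unshifted lists were called.

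The alternatives set at that stage were quantile normalization, centring of each array on its median, no filter, a filter at the 70th percentile, array weights, no intensity trend, a fold threshold, 1 probe set per gene, the 6 arrays of a contrast alone, a block for the replicate number, and leaving out each replicate. The background range, cyclic loess normalization, a fit without the L(3)MBT arrays and a block within 6 arrays were chosen after seeing the data. No pseudocount was needed, as the values were logarithms.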

Results

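RNA levels were measured in Kc cells, a Drosophila line derived from embryos that resembles blood cells (hemocytes), 4 days after RNA interference (RNAi). The 30 arrays fell into 10 groups of 3: a control that received a nonspecific RNA made from a plasmid, and knockdowns of Mip40, Mip120, Mip130, Lin-52, Myb, E2F2, both RBFs (RBF1 and RBF2 together), L(3)MBT and E2F1. The series concerns the Myb-MuvB or dREAM complex, a chromatin-bound regulator of transcription, and each comparison with the control asks which transcripts change when a subunit or partner is depleted. Signals were on a log2 scale, with array medians from 6.45 to 6.58, and the number of arrays limits the precision. In every comparison 7794 probe sets, covering 6393 genes, were tested. Changes below are log2 differences between group means; the values in parentheses are the mean ± SD (n = 3) of each group, or the standard error (SE) of the change. The 23 control probe sets without a target in flies had means from 3.16 to 6.22 in control. A signal in such a range can be background, so a change of a gene whose lower mean lies there is a lower bound. This applies to 94 of 482 named pairs of gene and comparison, among them all those of Gr63a, vas, CG5592, CG5250 and CG11052. In 11, such as vas after Mip40 and eater after E2F2 knockdown, both means lay there, and the change bounds nothing.

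All 8 target transcripts tested were lower in their own knockdown. The E2f2 transcript fell by 2.37 (6.32 ± 0.21 against 8.69 ± 0.16 in control, SD, n = 3), to 19.3% of control, with an adjusted p of 4.33e-19. The mip40 transcript fell by 2.00 (7.40 ± 0.11 against 9.40 ± 0.12), to 25.0%, and lin-52 fell by 1.71 (6.0 ± 0.07 against 7.71 ± 0.06), to 30.6%. E2f1 fell by 1.22 (7.61 ± 0.06 against 8.83 ± 0.20), to 42.9%, and mip120 fell by 0.92 (7.02 ± 0.18 against 7.94 ± 0.21), to 52.8%. Smaller falls were measured for mip130, by 0.49 (5.78 ± 0.10 against 6.26 ± 0.17), Rbf2, by 0.44 (7.10 ± 0.05 against 7.54 ± 0.04), and l(3)mbt, by 0.36 (6.37 ± 0.05 against 6.73 ± 0.11), to 71.3%, 73.7% and 78.1% of control. Their adjusted p values were 1.17e-05, 8.02e-07 and 6.98e-05. Genes near the level of l(3)mbt had a median of -0.14 on the L(3)MBT arrays, which may be part of its fall. Rbf was too weak to be tested (4.87 ± 0.10 in the RBFs knockdown against 4.92 ± 0.06), and no probe set could be assigned to Myb. A probe set inside the double-stranded RNA could read the added RNA, whose position is not given.

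**Figure D1:**
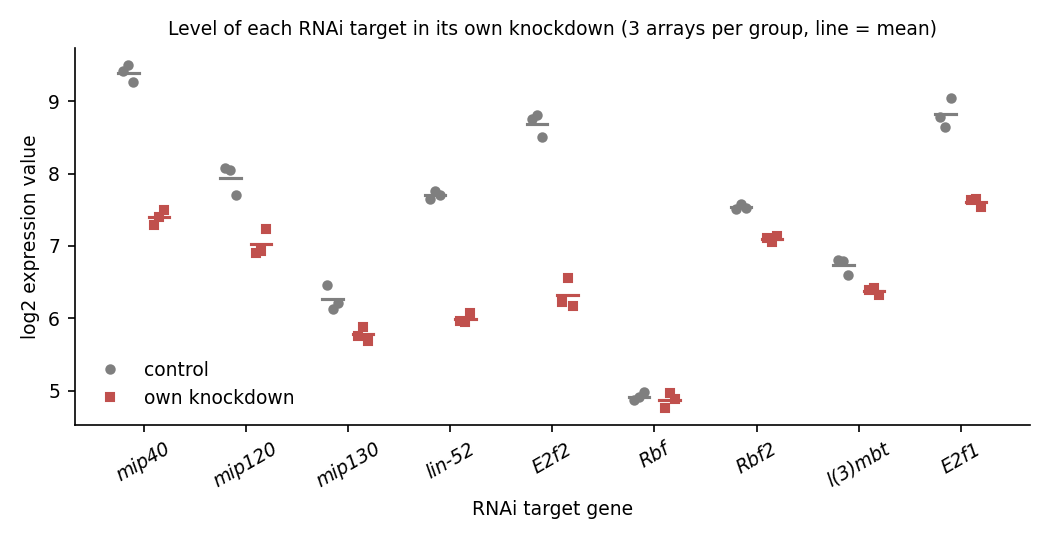
Signal (log2) of the RNAi target transcripts on each array, with control arrays beside the arrays of the gene's own knockdown; points are arrays and bars are means (n = 3). E2f2 fell by 2.37 and l(3)mbt fell by 0.36, the largest and the smallest change among the targets that were tested.

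**Figure D2:**
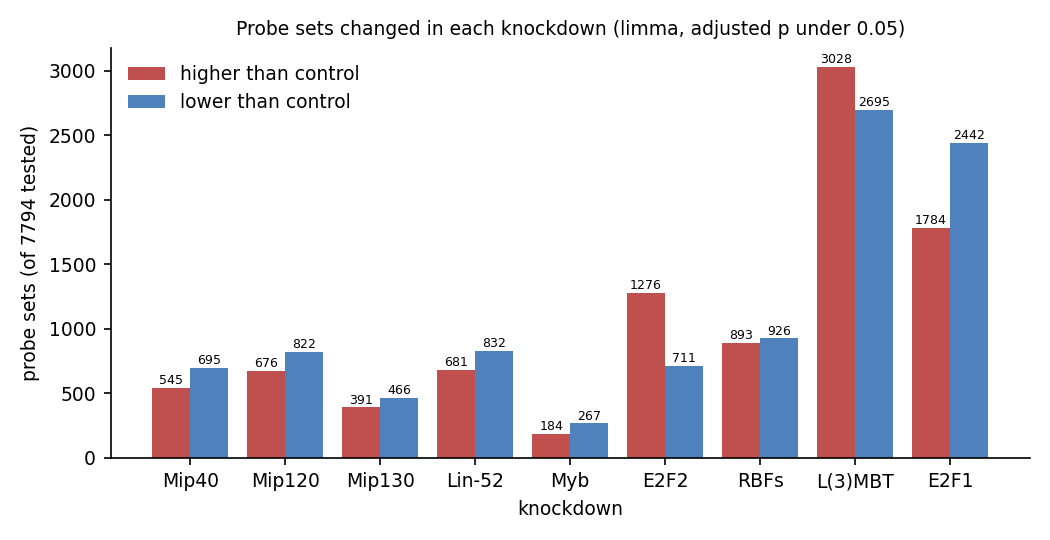
Number of probe sets higher and lower than control in each knockdown (adjusted p under 0.05). Counts ran from 451 after Myb to 5723 after L(3)MBT knockdown, of 7794 tested.

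Mip40 is a subunit of the MuvB core. After its knockdown Pxt, a cyclooxygenase-like peroxidase, rose by 2.24 (9.74 ± 0.11 against 7.51 ± 0.30). The Arp2/3 subunit paralog Arpc3B rose by 1.73 (8.51 ± 0.09 against 6.78 ± 0.20), and hdm, a gene of meiotic recombination, by 1.62 (7.59 ± 0.09 against 5.97 ± 0.05). CG6330 and CG31100 rose by 1.99 (10.00 ± 0.06 against 8.01 ± 0.41) and 1.62 (7.27 ± 0.07 against 5.65 ± 0.05). The extracellular matrix genes Tig (tiggrin), vkg and Col4a1 (both type IV collagen) changed by -1.88 (6.64 ± 0.11 against 8.52 ± 0.11), -1.80 (6.99 ± 0.08 against 8.79 ± 0.17) and -1.80 (7.39 ± 0.05 against 9.19 ± 0.15). CG34437 changed by -2.13 (4.49 ± 0.17 against 6.61 ± 0.39). Adjusted p for these genes ran from 9.81e-19 to 6.81e-10. In all, 1240 probe sets changed, 545 higher and 695 lower, and 43 of them by at least 2-fold.

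Of the germ line and piRNA pathway genes 7 rose and 2 fell of 30 measured (9 and 2 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0038, and adjusted p = 0.301 with an estimated correlation). They included swa, which localizes bicoid mRNA, 1.60 (SE 0.126), the piRNA factor tej, 1.35 (SE 0.131), and the germ line helicase vas, 0.84 (SE 0.126). Of the hemocyte genes 3 rose and 8 fell of 23 measured (3 and 9 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.00109, and adjusted p = 0.241 with an estimated correlation), among them the peroxidasin gene Pxn, -1.49 (SE 0.132), beside the collagens. Of the DNA damage and apoptosis genes 5 rose and 0 fell of 18 measured (7 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0133, and adjusted p = 0.464 with an estimated correlation). Irbp changed by 0.37 (SE 0.0827) and Ku80 0.34 (SE 0.0692), which encode the Ku complex of end joining, and rad50 0.32 (SE 0.0784). Of the mitosis genes 0 rose and 7 fell of 39 measured (0 and 11 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0188, and adjusted p = 0.729 with an estimated correlation). The checkpoint gene mad2 changed by -0.40 (SE 0.0771) and the mitotic kinesins Klp61F -0.37 (SE 0.0617) and Klp67A -0.28 (SE 0.0742). Of the oxidative phosphorylation genes 0 rose and 4 fell of 54 measured (0 and 3 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.00224, and adjusted p = 0.759 with an estimated correlation). The complex I subunits ND-15 changed by -0.49 (SE 0.0965), ND-B14.5A -0.37 (SE 0.0824) and ND-B14.5B -0.34 (SE 0.0925).

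Lists without a call but with at least 3 called genes had camera adjusted p from 0.0698 to 0.918. In the centrosome and centriole list 1 rose and 2 fell (Rcd4 -0.25), in DNA replication 4 rose and 0 fell (RPA3 0.27), and in meiosis and testis genes 4 rose and 0 fell (achi 0.47). For muscle genes 1 rose and 2 fell (Act79B -0.36), for immune genes 2 rose and 3 fell (spz -1.09), and for heat shock and stress genes 4 rose and 2 fell (Hsc70-3 -0.29). Of ribosomal protein genes 2 rose and 1 fell (RpS5b 1.18), where RpS5b is a paralog of RpS5a, and of proteasome genes 1 rose and 4 fell (Prosbeta2R2 0.62), where Prosbeta2R2 is a testis paralog. The control probe sets moved too: the hybridization spikes had a median of -0.31 against control and the GAPDH probe sets 0.49. The call of the DNA damage list ended with array weights (adjusted p = 0.0552), without control replicate 3 (0.0668) and without Mip40 replicate 3 (0.0791), over a range of 0.00398 to 0.464. The mitosis call ended without control replicate 1 (0.0845) or 2 (0.136; range 0.000436 to 0.729), and that of oxidative phosphorylation with fry (0.107) and without control replicate 1 (0.0675; range 6.22e-05 to 0.759). Single genes lost theirs as well: Klp67A without control replicate 1 (0.0582) or Mip40 replicate 1 (0.0529; range 5.47e-05 to 0.0582). Rcd4 lost its call without control replicate 1 (0.0867) or 3 (0.056) or Mip40 replicate 2 (0.0645; range 0.00609 to 0.0867), and RPA3 without control replicate 3 (0.0838) or Mip40 replicate 3 (0.0883; range 0.000132 to 0.0883). ND-B14.5B lost its call without control replicate 1 (0.0567; range 2.96e-05 to 0.0567), and Hsc70-3 with quantile (0.0682) or cyclic loess (0.0566) normalization (range 0.000215 to 0.0682).

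Mip120 and Mip130, the fly relatives of Lin-54 and Lin-9, belong to the same core. After Mip120 knockdown CG5592 rose by 3.56 (8.33 ± 0.09 against 4.77 ± 0.11), the carbon dioxide receptor gene Gr63a by 3.03 (6.79 ± 0.15 against 3.75 ± 0.18) and tej by 2.91 (8.05 ± 0.10 against 5.14 ± 0.20). CG5250 rose by 2.86 (8.42 ± 0.02 against 5.56 ± 0.26) and Pxt by 2.77 (10.28 ± 0.04 against 7.51 ± 0.30). The stathmin gene stai and the syndecan gene Sdc changed by -1.49 (5.43 ± 0.18 against 6.92 ± 0.23) and -1.36 (6.66 ± 0.10 against 8.02 ± 0.08). Falls of CG4872, CG2930 and CG4829 were -1.35 (5.42 ± 0.07 against 6.77 ± 0.19), -1.24 (8.22 ± 0.10 against 9.45 ± 0.33) and -1.07 (6.91 ± 0.05 against 7.98 ± 0.34). The adjusted p of these genes ran from 3.17e-24 to 4.18e-07. Altogether 1498 probe sets changed, 676 higher and 822 lower, and 54 by at least 2-fold.

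In the germ line and piRNA list 7 rose and 3 fell of 30 measured (7 and 3 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.0108, and adjusted p = 0.409 with an estimated correlation); vas rose by 2.46 (SE 0.126) and swa by 1.35 (SE 0.126). In the mitosis list 0 rose and 17 fell of 39 measured (0 and 19 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 3.87e-07, and adjusted p = 0.4 with an estimated correlation). Klp61F changed by -0.63 (SE 0.0617), the anillin gene scra -0.61 (SE 0.0624) and the cytokinesis gene tum -0.60 (SE 0.0655). In the proteasome list 2 rose and 22 fell of 29 measured (2 and 24 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 3.87e-07, and adjusted p = 0.464 with an estimated correlation). Prosbeta5, a catalytic subunit, changed by -0.52 (SE 0.0922), and the genes that rose were the testis paralogs Rpt3R 0.82 (SE 0.0964) and Prosbeta2R2 0.68 (SE 0.0798). In the oxidative phosphorylation list 0 rose and 12 fell of 54 measured (0 and 12 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.00135, and adjusted p = 0.744 with an estimated correlation). ATPsynepsilonL changed by -0.59 (SE 0.0743), ATPsynC -0.44 (SE 0.0783) and ND-B14.5B -0.49 (SE 0.0925).

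Among lists that were not called (camera adjusted p 0.0945 to 0.828), dREAM genes had 4 rises and 1 fall (mip120 -0.92), DNA replication genes had 5 rises and 4 falls (Slbp -0.35), and DNA damage genes had 2 rises and 1 fall (egr 0.39). Hemocyte genes had 2 rises and 6 falls (Col4a1 -1.07), immune genes had 0 rises and 4 falls (cact -0.42), and Hippo pathway genes had 3 rises and 0 falls (Mer 0.25). Heat shock genes had 4 rises and 0 falls (DnaJ-1 0.55), RNA interference genes had 1 rise and 2 falls (vig 0.34), and ribosomal protein genes had 1 rise and 7 falls (RpLP0-like -0.47). The oxidative phosphorylation call ended with fry (adjusted p = 0.0796, range 6.43e-05 to 0.744).

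After Mip130 knockdown the same comparison showed rises of CG5592 by 3.33 (8.10 ± 0.11 against 4.77 ± 0.11), Gr63a by 2.96 (6.71 ± 0.27 against 3.75 ± 0.18) and Pxt by 2.90 (10.40 ± 0.07 against 7.51 ± 0.30). The germ line genes tej and vas rose by 2.80 (7.94 ± 0.09 against 5.14 ± 0.20) and 2.79 (7.54 ± 0.10 against 4.75 ± 0.14). Pxn changed by -1.85 (8.11 ± 0.04 against 9.96 ± 0.29), stai by -1.15 (5.76 ± 0.14 against 6.92 ± 0.23) and CG31549 by -1.09 (8.26 ± 0.23 against 9.35 ± 0.02). Falls were also measured for the acetylcholine receptor subunit gene nAChRbeta3, -1.04 (8.75 ± 0.08 against 9.79 ± 0.13), and vkg, -0.96 (7.83 ± 0.06 against 8.79 ± 0.17). Adjusted p ran from 2.34e-23 to 3.34e-10. Changed probe sets numbered 857, 391 higher and 466 lower, of which 50 by at least 2-fold. The count was 566 without control replicate 1.

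Of germ line and piRNA genes 8 rose and 3 fell of 30 measured (8 and 5 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.0038, and adjusted p = 0.301 with an estimated correlation), including swa 1.42 (SE 0.126). For hemocyte genes 2 rose and 6 fell of 23 measured (2 and 7 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.00941, and adjusted p = 0.295 with an estimated correlation). Col4a1 changed by -0.95 (SE 0.0661) beside Pxn and vkg. For mitosis genes 0 rose and 16 fell of 39 measured (1 and 22 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 5.19e-09, and adjusted p = 0.301 with an estimated correlation). The gene tum changed by -0.60 (SE 0.0655), scra -0.59 (SE 0.0624) and Klp61F -0.56 (SE 0.0617). For proteasome genes 2 rose and 7 fell of 29 measured (2 and 17 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.0038, and adjusted p = 0.722 with an estimated correlation). The rises were those of the paralogs Rpt3R 0.85 (SE 0.0964) and Prosbeta2R2 0.76 (SE 0.0798), and Prosbeta5 changed by -0.32 (SE 0.0922). For oxidative phosphorylation genes 0 rose and 9 fell of 54 measured (0 and 9 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.000157, and adjusted p = 0.722 with an estimated correlation). ND-15 changed by -0.59 (SE 0.0965), ATPsynC -0.48 (SE 0.0783) and ND-B14.5B -0.32 (SE 0.0925).

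The lists not called (camera adjusted p 0.114 to 0.836) included centrosome genes, of which 2 rose and 1 fell (asl -0.28), DNA replication genes, of which 3 rose and 2 fell (dUTPase -0.36), and DNA damage genes, of which 5 rose and 0 fell (egr 0.56); egr encodes a tumour necrosis factor. They also included meiosis and testis genes, of which 3 rose and 0 fell (topi 0.36), immune genes, of which 0 rose and 3 fell (cact -0.48), and heat shock genes, of which 3 rose and 0 fell (Cat 0.47). The oxidative phosphorylation and proteasome calls ended with fry (adjusted p = 0.0697, range 1.36e-05 to 0.722, and 0.0941, range 0.000598 to 0.722). Without single arrays the following genes lost their calls. For asl it was without control replicate 1 (0.242) or Mip130 replicate 2 (0.0912) or 3 (0.135; range 0.000788 to 0.242). For Prosbeta5 it was without control replicate 1 (0.112) or 2 (0.0652) or Mip130 replicate 1 (0.2; range 0.000464 to 0.2), and ND-B14.5B without control replicate 1 (0.106) or 2 (0.075) or Mip130 replicate 1 (0.17; range 0.000224 to 0.17).

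Lin-52 is another subunit of the core. After its knockdown superdeath rose by 1.87 (7.61 ± 0.12 against 5.74 ± 0.12), hdm by 1.72 (7.70 ± 0.30 against 5.97 ± 0.05) and swa by 1.71 (7.04 ± 0.19 against 5.33 ± 0.25). CG44325 rose by 1.48 (9.08 ± 0.21 against 7.60 ± 0.10) and CG5080 by 1.41 (9.41 ± 0.23 against 8.0 ± 0.11). Beside lin-52 itself, the ceramidase gene CDase changed by -1.69 (5.63 ± 0.07 against 7.31 ± 0.09) and the lysosomal cystine transporter gene Ctns by -1.64 (8.21 ± 0.52 against 9.85 ± 0.20). The matrix gene Ppn (papilin) changed by -1.59 (9.36 ± 0.55 against 10.95 ± 0.16) and vkg by -1.52 (7.27 ± 0.14 against 8.79 ± 0.17). The adjusted p ran from 7.13e-18 to 2.36e-10. The 1513 changed probe sets were 681 higher and 832 lower, and 34 changed by at least 2-fold; the count was 639 with the 6 arrays alone.

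Of 30 germ line genes, vas 1.55 (SE 0.126) and tej 1.17 (SE 0.131) rose beside swa: 10 rose and 5 fell of 30 measured (11 and 5 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.0264, and adjusted p = 0.464 with an estimated correlation). Hemocyte genes moved both ways: 2 rose and 8 fell of 23 measured (2 and 9 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00103, and adjusted p = 0.241 with an estimated correlation). Pxn changed by -1.44 (SE 0.132) beside Ppn and vkg. The mitosis list was lower: 0 rose and 14 fell of 39 measured (2 and 21 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.00135, and adjusted p = 0.598 with an estimated correlation). Klp61F changed by -0.62 (SE 0.0617), feo -0.45 (SE 0.064) and Klp67A -0.45 (SE 0.0742). For the DNA replication list 13 rose and 1 fell of 48 measured (15 and 2 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.0038, and adjusted p = 0.722 with an estimated correlation). Its largest changes were the S phase cyclin gene CycE 0.43 (SE 0.149), the deoxyribonucleoside kinase gene dnk 0.28 (SE 0.0726) and Psf2 -0.29 (SE 0.0693). For heat shock and stress genes 6 rose and 1 fell of 21 measured (6 and 1 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.0187, and adjusted p = 0.241 with an estimated correlation). The chaperone genes Hsp27 changed by 0.92 (SE 0.146) and DnaJ-1 0.48 (SE 0.0792) and the metallothionein gene MtnA 0.32 (SE 0.094). Proteasome genes were lower: 0 rose and 16 fell of 29 measured (0 and 19 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 2.8e-06, and adjusted p = 0.486 with an estimated correlation). Prosbeta3 changed by -0.40 (SE 0.103), Prosbeta7 -0.36 (SE 0.0921) and Rpn12 -0.35 (SE 0.0919).

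Without a call of the list (camera adjusted p 0.0945 to 0.861), the dREAM list had 1 rise and 2 falls (lin-52 -1.71), centrosome genes had 1 rise and 4 falls (SAK -0.35), and DNA damage genes had 1 rise and 2 falls (egr -0.77). Immune genes had 1 rise and 4 falls (Tep4 0.51), ecdysone response genes had 1 rise and 2 falls (MsrA -0.83), and RNA interference genes had 3 rises and 1 fall (Fmr1 0.50). Ribosomal protein genes had 0 rises and 5 falls (RpS19b -0.72) and oxidative phosphorylation genes had 1 rise and 6 falls (ND-15 -0.49). The hybridization spikes had a median of -0.30 against control, and the GAPDH probe sets 0.54. List calls ended as follows: DNA replication with array weights (adjusted p = 0.228), fry (0.0958) and without control replicate 3 (0.129) or Lin-52 replicate 1 (0.0683; range 0.000222 to 0.722). That of the germ line list ended with cyclic loess (0.0539), array weights (0.0546) and without Lin-52 replicate 1 (0.062; range 0.00114 to 0.464), and that of heat shock without Lin-52 replicate 1 (0.148; range 0.000382 to 0.241). Gene calls ended for CycE without control replicate 1 (0.0616) or 3 (0.183) or Lin-52 replicate 1 (0.365; range 0.00704 to 0.365). The call of dnk ended without Lin-52 replicate 1 (0.089; range 0.000168 to 0.156), that of MtnA without control replicate 3 (0.0517) or Lin-52 replicate 1 (0.155; range 0.0075 to 0.155), and those of Prosbeta3 (0.0631; range 2.64e-07 to 0.0834) and Rpn12 (0.0566; range 2.93e-06 to 0.0591) without Lin-52 replicate 2. In a fit of the 6 arrays alone CycE (0.183), dnk (0.156), MtnA (0.0984), Prosbeta3 (0.0834), Rpn12 (0.0591) and ND-15 (0.0537) were not called. Nor was CycE with centring (0.0578), cyclic loess (0.0569) or array weights (0.264), or MtnA with array weights (0.0861).

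Myb is the DNA-binding activator in the complex. After its knockdown Arpc3B rose by 2.05 (8.83 ± 0.31 against 6.78 ± 0.20), CG13148 by 1.48 (7.01 ± 0.15 against 5.54 ± 0.17) and superdeath by 1.48 (7.22 ± 0.13 against 5.74 ± 0.12). Rises of swa and hdm were 1.46 (6.80 ± 0.23 against 5.33 ± 0.25) and 1.36 (7.33 ± 0.08 against 5.97 ± 0.05). The stathmin gene stai changed by -2.14 (4.78 ± 0.15 against 6.92 ± 0.23), nAChRbeta3 by -1.44 (8.35 ± 0.05 against 9.79 ± 0.13) and NtR by -1.28 (7.61 ± 0.07 against 8.88 ± 0.12). Falls of regucalcin and CG3505 were -1.23 (8.50 ± 0.07 against 9.73 ± 0.02) and -1.21 (7.11 ± 0.24 against 8.32 ± 0.11). Adjusted p values ran from 2.11e-17 to 4.04e-10. This knockdown changed 451 probe sets, 184 higher and 267 lower, and 23 by at least 2-fold.

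The DNA replication list was called in the upward direction: 17 rose and 1 fell of 48 measured (29 and 1 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 7.94e-16, and adjusted p = 0.241 with an estimated correlation). The gene dnk rose by 0.63 (SE 0.0726) and CycE by 0.60 (SE 0.149), and the GINS subunit gene Psf2 changed by -0.41 (SE 0.0693). The mitosis list was called in the downward direction: 0 rose and 14 fell of 39 measured (1 and 18 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 9.68e-12, and adjusted p = 0.241 with an estimated correlation). The gene tum changed by -0.63 (SE 0.0655), Klp61F -0.59 (SE 0.0617) and the kinase gene aurB -0.57 (SE 0.0872). Of the hemocyte genes measured, Pxn -1.03 (SE 0.132), Nplp2 -0.94 (SE 0.126) and NimB5 -0.59 (SE 0.127) moved most: 1 rose and 5 fell of 23 measured (1 and 8 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.00183, and adjusted p = 0.241 with an estimated correlation). Germ line genes had 4 rises and 2 falls (swa 1.46) without a call (camera adjusted p = 0.306), among them squ -0.81 (SE 0.0636) and spn-E -0.54 (SE 0.0797), both of the piRNA pathway. The CycE call ended without control replicate 3 (0.079) or Myb replicate 3 (0.0841; range 0.00614 to 0.0841). Within the 6 arrays, where the replicate numbers of control and Myb arrays correlated, a block for the replicate number gave 543 changed probe sets, and no block 200. With array weights the count for Myb was 766.

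E2F2 is the repressor E2F of flies. After its knockdown Gr63a rose by 3.30 (7.06 ± 0.08 against 3.75 ± 0.18), vas by 2.97 (7.72 ± 0.03 against 4.75 ± 0.14) and CG5250 by 2.74 (8.29 ± 0.08 against 5.56 ± 0.26). CG5592 rose by 2.54 (7.31 ± 0.10 against 4.77 ± 0.11) and CG5080 by 1.74 (9.73 ± 0.03 against 8.0 ± 0.11). Falls were smaller apart from that of E2f2 itself: Arpc3B changed by -0.91 (5.87 ± 0.11 against 6.78 ± 0.20) and gNacalpha by -0.86 (6.09 ± 0.05 against 6.95 ± 0.25). RpS5b changed by -0.79 (7.67 ± 0.04 against 8.47 ± 0.21) and CG14434 by -0.78 (8.13 ± 0.05 against 8.92 ± 0.19). The adjusted p of these genes ran from 5.84e-20 to 0.000122. Of 1987 changed probe sets 1276 were higher and 711 lower. Among the 23 that changed by at least 2-fold, 22 were higher. The share higher, 64.2%, depended on scaling: it was 50.5% after quantile normalization and 77.2% after centring each array on its median.

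The hemocyte list was higher: 11 rose and 0 fell of 23 measured (11 and 1 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0038, and adjusted p = 0.241 with an estimated correlation). The phagocytosis receptor gene eater changed by 0.75 (SE 0.183), Pxn 0.74 (SE 0.132) and Nplp2 0.70 (SE 0.126). The DNA damage list was higher too: 6 rose and 1 fell of 18 measured (7 and 1 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.0224, and adjusted p = 0.486 with an estimated correlation). The ATM kinase gene tefu changed by 0.60 (SE 0.0859), mre11 0.33 (SE 0.065) and Dark 0.27 (SE 0.0739). Oxidative phosphorylation genes went both ways: 4 rose and 10 fell of 54 measured (4 and 10 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.0377, and adjusted p = 0.848 with an estimated correlation). The paralog COX4L changed by -0.86 (SE 0.0912), ATPsynepsilonL -0.52 (SE 0.0743) and COX7A 0.32 (SE 0.0772).

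Lists without a call had camera adjusted p from 0.0789 to 0.946. Mitosis genes had 10 rises and 1 fall (fzy 0.67), where fzy encodes the Cdc20 activator of mitotic exit, germ line genes had 8 rises and 8 falls (vas 2.97), and centrosome genes had 3 rises and 0 falls (ana2 0.32). DNA replication genes had 4 rises and 2 falls (Mcm6 0.34), meiosis and testis genes had 3 rises and 1 fall (bol 0.37), and neuronal genes had 1 rise and 2 falls (Csp 0.48). Fat body and gut genes had 0 rises and 5 falls (Mal-A1 -0.25), immune genes had 3 rises and 1 fall (puc 0.45), and ecdysone response genes had 1 rise and 2 falls (Cth 0.50). Patterning genes had 1 rise and 3 falls (aop 0.26), Hippo pathway genes had 3 rises and 1 fall (mats 0.26), and heat shock genes had 5 rises and 0 falls (Cat 0.50). RNA interference genes had 4 rises and 0 falls (vig 0.39), ribosomal protein genes had 2 rises and 6 falls (RpS5b -0.79), and proteasome genes had 3 rises and 4 falls (Rpt3R 1.19), where Rpt3R is a testis paralog. The dREAM list had 2 rises and 1 fall (E2f2 -2.37). The DNA damage call ended without control replicate 3 (adjusted p = 0.0541, range 0.0013 to 0.486), and that of oxidative phosphorylation with fry (0.328) and without control replicate 1 (0.317) or E2F2 replicate 1 (0.099; range 4.27e-05 to 0.848). Mal-A1 lost its call without control replicate 3 (0.0542, range 0.00309 to 0.0542), and aop without control replicate 2 (0.0625) or 3 (0.202) or E2F2 replicate 1 (0.0853), 2 (0.0812) or 3 (0.0955; range 0.0138 to 0.202).

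RBF1 and RBF2 are the fly relatives of the retinoblastoma protein, which bind E2F factors. After their knockdown vas rose by 3.00 (7.75 ± 0.27 against 4.75 ± 0.14), CG5592 by 2.52 (7.29 ± 0.12 against 4.77 ± 0.11) and CG5250 by 1.97 (7.52 ± 0.05 against 5.56 ± 0.26). Rises of CG7997 and CG5080 were 1.58 (9.67 ± 0.08 against 8.09 ± 0.10) and 1.54 (9.54 ± 0.06 against 8.0 ± 0.11). The 5 largest falls were all in matrix genes. Ppn changed by -2.0 (8.95 ± 0.02 against 10.95 ± 0.16), Col4a1 by -1.98 (7.21 ± 0.04 against 9.19 ± 0.15) and Tig by -1.65 (6.87 ± 0.11 against 8.52 ± 0.11). Pxn changed by -1.62 (8.34 ± 0.10 against 9.96 ± 0.29) and vkg by -1.60 (7.19 ± 0.10 against 8.79 ± 0.17). The adjusted p ranged from 3.97e-20 to 1e-10. The comparison counted 1819 changed probe sets, 893 higher and 926 lower, and 35 by at least 2-fold.

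These matrix genes belonged to a hemocyte list that moved both ways: 4 rose and 6 fell of 23 measured (4 and 6 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.00958, and adjusted p = 0.295 with an estimated correlation). Proteasome genes were mostly lower: 2 rose and 21 fell of 29 measured (3 and 21 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 4.63e-07, and adjusted p = 0.464 with an estimated correlation). Rpn12 changed by -0.58 (SE 0.0919) and Prosbeta3 -0.49 (SE 0.103), while the paralog Rpt3R changed by 0.66 (SE 0.0964). The oxidative phosphorylation list was lower: 0 rose and 21 fell of 54 measured (0 and 27 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 2.8e-06, and adjusted p = 0.618 with an estimated correlation). ND-B14.5A changed by -0.63 (SE 0.0824), COX4L -0.41 (SE 0.0912) and COX5A -0.41 (SE 0.076). The DNA replication list was higher: 16 rose and 3 fell of 48 measured (16 and 3 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.0342, and adjusted p = 0.793 with an estimated correlation). CycE changed by 0.59 (SE 0.149), Mcm10 0.39 (SE 0.125) and dup 0.37 (SE 0.0819), the fly Cdt1 of origin licensing.

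Uncalled lists (camera adjusted p 0.0621 to 0.918) were mitosis, where 6 rose and 2 fell (tws 0.46), centrosome, where 3 rose and 2 fell (asl -0.28), and DNA damage, where 8 rose and 1 fell (egr -0.44). Others were germ line, where 8 rose and 3 fell (vas 3.00), meiosis and testis, where 3 rose and 0 fell (bol 0.76), and immune genes, where 2 rose and 4 fell (Tep4 0.62). In ecdysone response genes 1 rose and 2 fell (ImpL2 0.50), in Hippo pathway genes 5 rose and 0 fell (CycE 0.59), in heat shock genes 4 rose and 0 fell (crc 0.37), and in ribosomal protein genes 2 rose and 4 fell (RpS5b -0.50). The GAPDH control probe sets had a median of 0.54 against control. The DNA replication call ended with array weights (adjusted p = 0.328), fry (0.108) and without control replicate 3 (0.36) or RBFs replicate 1 (0.162; range 0.00329 to 0.793). Calls of single genes ended for Mcm10 without control replicate 2 (0.0514) or 3 (0.102) or RBFs replicate 1 (0.18; range 0.0113 to 0.18) and for asl without control replicate 1 (0.147) or RBFs replicate 2 (0.0934; range 0.00131 to 0.147).

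L(3)MBT is a chromatin protein with MBT repeats. After its knockdown CG11052 rose by 2.88 (6.64 ± 0.10 against 3.76 ± 0.08), the ribosomal protein paralog RpS5b by 2.51 (10.98 ± 0.05 against 8.47 ± 0.21) and the elongation factor gene eEF1alpha2 by 2.19 (8.65 ± 0.02 against 6.46 ± 0.16). CG5080 rose by 2.08 (10.08 ± 0.03 against 8.0 ± 0.11) and the glycolytic enzyme gene Pfk by 2.07 (9.49 ± 0.06 against 7.42 ± 0.02). Ppn changed by -1.97 (8.99 ± 0.12 against 10.95 ± 0.16), Col4a1 by -1.70 (7.49 ± 0.09 against 9.19 ± 0.15) and the immune peptide gene BomS5 by -1.53 (5.70 ± 0.08 against 7.23 ± 0.13). The collagen gene vkg changed by -1.44 (7.36 ± 0.05 against 8.79 ± 0.17) and the ATP synthase subunit gene ATPsynD by -1.36 (9.49 ± 0.02 against 10.85 ± 0.06). Adjusted p for these ran from 3.87e-22 to 3.09e-13. The changed probe sets numbered 5723, 3028 higher and 2695 lower, and 183 of the 213 that changed by at least 2-fold were higher. The 3 arrays of this group stood apart: the 18S ribosomal RNA control probe sets were 2.65 to 5.45 above control, the mean SD of signals within an array was 1.87 against 1.75, and over 10 classes of genes by control level the median change was 0.09 in the dimmest, -0.14 in the second and 0.22 in the brightest (-0.13 in the dimmest of all probe sets without the filter). The share higher, 52.9%, became 65.3% after centring each array on its median, which moved the median of all changes to 0.10.

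**Figure D3:**
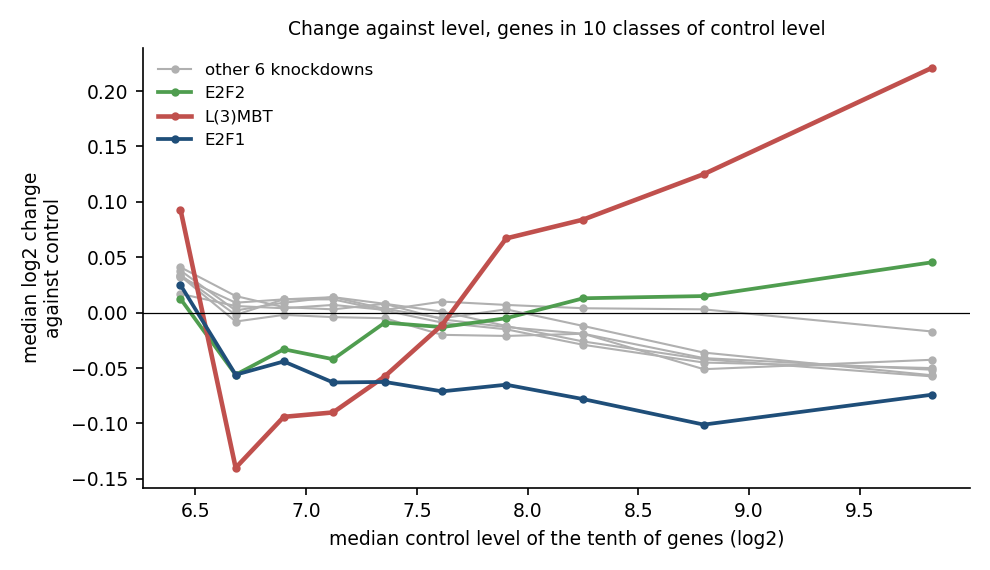
Median log2 change against control of genes in 10 classes of control signal, for each knockdown. For L(3)MBT it is 0.09 in the dimmest class, -0.14 in the second and 0.22 in the brightest.

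DNA replication genes were mostly higher: 29 rose and 2 fell of 48 measured (29 and 2 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00467, and adjusted p = 0.722 with an estimated correlation). CycE changed by 1.26 (SE 0.149), dup 1.26 (SE 0.0819) and the clamp loader gene Gnf1 0.80 (SE 0.0761). So were mitosis genes: 26 rose and 1 fell of 39 measured (26 and 1 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.00173, and adjusted p = 0.614 with an estimated correlation). The microtubule gene msps changed by 0.72 (SE 0.0839), Incenp 0.72 (SE 0.082) and feo 0.71 (SE 0.064). Oxidative phosphorylation genes were mostly higher too: 41 rose and 5 fell of 54 measured (43 and 5 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.000353, and adjusted p = 0.722 with an estimated correlation). ATPsynD changed by -1.36 (SE 0.0615), ND-B17.2 1.36 (SE 0.0812) and ATPsynC 1.10 (SE 0.0783). Of the ribosomal protein genes 24 rose and 2 fell of 34 measured (24 and 2 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.00173, and adjusted p = 0.598 with an estimated correlation). RpS5b changed by 2.51 (SE 0.0979), RpS19b 0.92 (SE 0.0964) and RpL29 0.81 (SE 0.0749); after cyclic loess normalization their median was -0.045. Fat body and gut genes were lower: 0 rose and 12 fell of 17 measured (0 and 12 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.00103, and adjusted p = 0.241 with an estimated correlation). The lysozyme genes LysB changed by -0.88 (SE 0.0597) and LysX -0.76 (SE 0.081) and the lipid transfer gene Mtp -0.54 (SE 0.0729). Muscle genes were mostly lower: 1 rose and 11 fell of 12 measured (1 and 11 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.0199, and adjusted p = 0.409 with an estimated correlation). Act87E changed by -0.56 (SE 0.047), Mlc2 0.51 (SE 0.0725) and Strn-Mlck -0.45 (SE 0.0608).

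Camera adjusted p of the lists not called ran from 0.0671 to 0.616. Germ line genes had 17 rises and 4 falls (tej 1.63), DNA damage genes had 10 rises and 3 falls (p53 1.14), and proteasome genes had 19 rises and 2 falls (Rpt3R 0.74). Hemocyte genes had 9 rises and 10 falls (Ppn -1.97), heat shock genes had 13 rises and 3 falls (MtnA 1.39), and immune genes had 3 rises and 7 falls (Tep4 0.81). Ecdysone response genes had 2 rises and 6 falls (ImpL2 1.65), where ImpL2 binds insulin-like peptides, meiosis and testis genes had 3 rises and 7 falls (Mst84Dc -0.79), and patterning genes had 1 rise and 9 falls (gsb -0.36). Photoreceptor genes had 1 rise and 6 falls (rdgA -0.61), neuronal genes had 1 rise and 4 falls (Csp 0.76), and RNA interference genes had 5 rises and 0 falls (vig 0.94). Hippo pathway genes had 5 rises and 2 falls (CycE 1.26), centrosome genes had 5 rises and 1 fall (Cp110 0.52), and dREAM genes had 7 rises and 2 falls (mip120 0.56). Quantile normalization ended the calls of DNA replication (adjusted p = 0.083, range 2.33e-05 to 0.722), ribosomal proteins (0.327, range 1.87e-07 to 0.919) and oxidative phosphorylation (0.115, range 7.54e-05 to 0.722), and cyclic loess ended those of ribosomal proteins (0.919) and oxidative phosphorylation (0.108).

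E2F1 is the activator E2F of flies. After its knockdown the chitinase-like growth factor gene Idgf1 rose by 3.58 (8.38 ± 0.19 against 4.80 ± 0.38), the virus-induced gene vir-1 by 3.03 (9.83 ± 0.13 against 6.81 ± 0.04) and the GABA transaminase gene Gabat by 2.76 (8.75 ± 0.23 against 5.99 ± 0.04). CG6330 rose by 3.78 (11.80 ± 0.02 against 8.01 ± 0.41) and CG8066 by 2.69 (8.39 ± 0.06 against 5.69 ± 0.04). Pxn and Ppn changed by -2.62 (7.34 ± 0.12 against 9.96 ± 0.29) and -1.94 (9.01 ± 0.06 against 10.95 ± 0.16). The replication helicase subunit genes Mcm5 and Mcm2 changed by -1.90 (6.27 ± 0.21 against 8.17 ± 0.25) and -1.87 (6.77 ± 0.12 against 8.64 ± 0.09), and the sliding clamp gene PCNA by -1.80 (8.84 ± 0.04 against 10.64 ± 0.12). Their adjusted p ran from 5.35e-22 to 2.54e-13. The knockdown changed 4226 probe sets, 1784 higher and 2442 lower, and 213 of the 305 that changed by at least 2-fold were higher. The share higher, 42.2%, was 53% after cyclic loess normalization.

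The DNA replication list was called in the downward direction: 0 rose and 47 fell of 48 measured (0 and 47 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.84e-24, and adjusted p = 0.241 with an estimated correlation). Of mitosis genes 2 rose and 34 fell of 39 measured (2 and 34 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 7.4e-11, and adjusted p = 0.241 with an estimated correlation). Klp61F changed by -1.30 (SE 0.0617), the minus-end kinesin gene ncd -1.23 (SE 0.0606) and the condensin gene glu -1.19 (SE 0.0657). Of centrosome genes 0 rose and 9 fell of 12 measured (0 and 9 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.00183, and adjusted p = 0.241 with an estimated correlation). The gene spd-2 changed by -1.12 (SE 0.0534), Cp110 -1.02 (SE 0.0624) and asl -0.82 (SE 0.087). The dREAM list itself was lower: 0 rose and 7 fell of 10 measured (0 and 7 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 0.00291, and adjusted p = 0.295 with an estimated correlation). Caf1-55 changed by -0.87 (SE 0.0776) and Rbf2 -0.79 (SE 0.0571) beside E2f1. Immune genes were higher: 7 rose and 0 fell of 13 measured (7 and 0 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.00726, and adjusted p = 0.241 with an estimated correlation). Tep4 changed by 1.68 (SE 0.089), the attacin gene AttD 0.96 (SE 0.0872) and the JNK phosphatase gene puc 0.91 (SE 0.0993). The heat shock and stress list was higher: 10 rose and 2 fell of 21 measured (10 and 2 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.00651, and adjusted p = 0.241 with an estimated correlation). The glutathione transferase gene GstE1 changed by 1.17 (SE 0.0701), Hsp27 0.94 (SE 0.146) and MtnA 0.94 (SE 0.094). On these arrays all 9 hybridization spikes were below every control array (median -0.76), while the actin and GAPDH probe sets were above them (medians 0.76 and 1.10).

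For lists without a call the camera adjusted p ran from 0.0621 to 0.926. Hemocyte genes had 11 rises and 6 falls (Pxn -2.62), germ line genes had 7 rises and 9 falls (bam -1.08), and DNA damage genes had 4 rises and 6 falls (egr 1.73). Oxidative phosphorylation genes had 5 rises and 29 falls (ND-B14.5A -0.69), proteasome genes had 2 rises and 16 falls (Rpn12 -0.64), and ribosomal protein genes had 10 rises and 6 falls (RpLP0-like -0.58). Fat body and gut genes had 3 rises and 3 falls (Cyp6a9 2.23), where Cyp6a9 is a cytochrome P450, ecdysone response genes had 3 rises and 6 falls (ImpL2 2.04), and Hippo pathway genes had 5 rises and 3 falls (Mer 0.49). Meiosis and testis genes had 1 rise and 2 falls (bol 1.23), neuronal genes had 2 rises and 2 falls (Csp 0.95), and photoreceptor genes had 1 rise and 2 falls (toy 0.45). Muscle genes had 2 rises and 2 falls (Mlc2 0.68), and RNA interference genes had 3 rises and 1 fall (Dcr-2 0.71), where Dcr-2 cuts double-stranded RNA.

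**Figure D4:**
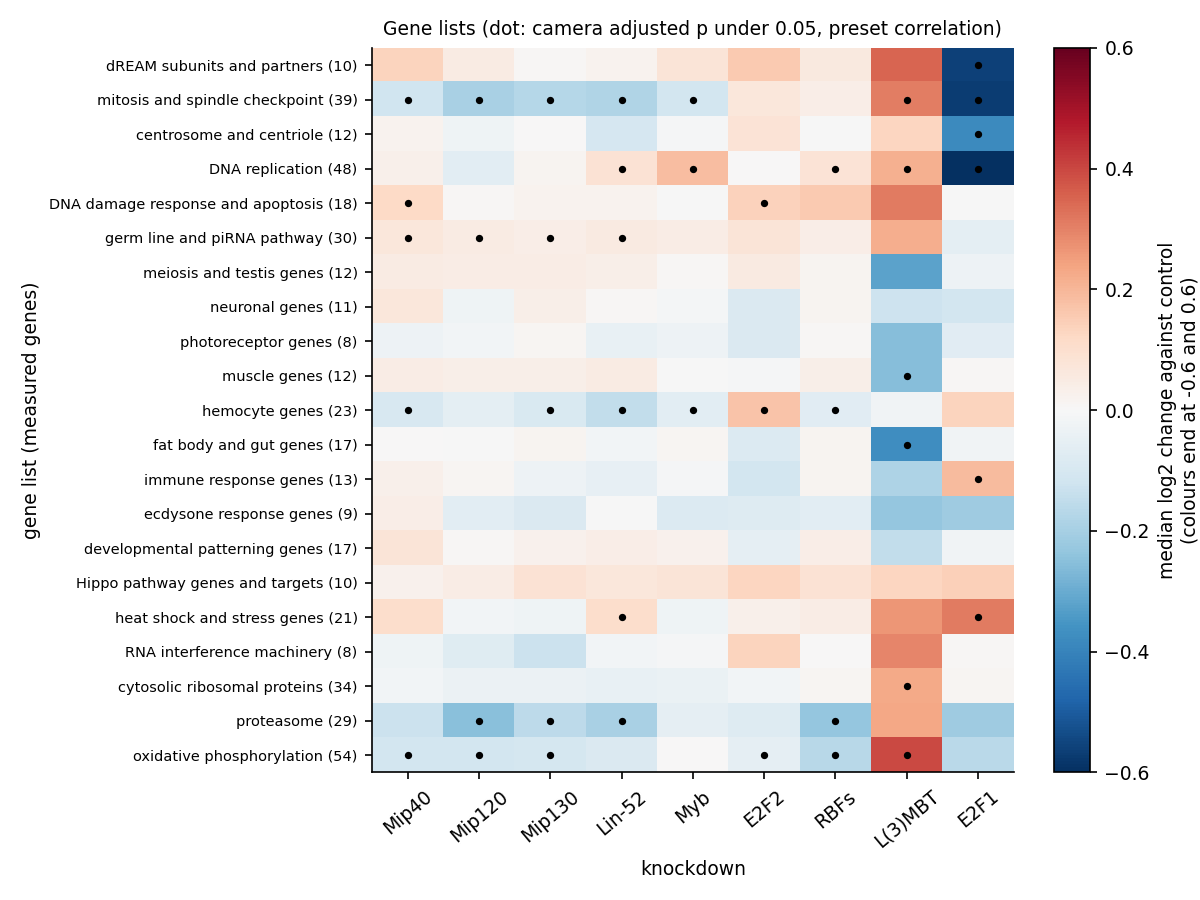
Median log2 change of each gene list in each knockdown against control, with called lists marked. DNA replication genes ran from -0.93 after E2F1 knockdown to 0.21 after L(3)MBT knockdown.

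A set of 7 lists was called in no knockdown, and the lowest camera adjusted p of each was as follows. It was 0.0978 for the 12 meiosis and testis genes (Mip40), 0.294 for the 11 neuronal genes (L(3)MBT) and 0.09 for the 8 photoreceptor genes (L(3)MBT). For the 9 ecdysone response genes it was 0.262 (Myb), for the 17 patterning genes 0.0978 (L(3)MBT), for the 10 Hippo pathway genes 0.0603 (Myb) and for the 8 RNA interference genes 0.0978 (L(3)MBT). Of 189 list tests 42 were called, 35 of these were also called in the same direction by fry, and 0 were called with an estimated correlation. Splits that mixed knockdown and control arrays called up to 11 lists (L(3)MBT), where the real split called 6.

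Direct contrasts between knockdowns did not use the means of the control arrays, which still entered the estimate of spread. Between the repressor and the activator E2F, vas was higher after E2F2 than after E2F1 knockdown by 3.51 (7.72 ± 0.03 against 4.21 ± 0.30), Pxn by 3.36 (10.71 ± 0.13 against 7.34 ± 0.12) and Gr63a by 3.26 (7.06 ± 0.08 against 3.79 ± 0.04). Lower were vir-1, by -3.77 (6.07 ± 0.19 against 9.83 ± 0.13), CG6330, by -3.55 (8.24 ± 0.29 against 11.80 ± 0.02), and Idgf1, by -3.08 (5.29 ± 0.02 against 8.38 ± 0.19). DNA replication genes were higher after E2F2 knockdown: 47 higher and 0 lower of 48, median 0.93 (camera adjusted p = 1.82e-26, and adjusted p = 0.0716 with an estimated correlation). So were mitosis genes: 37 higher and 0 lower of 39, median 0.67 (camera adjusted p = 2.76e-15, and adjusted p = 0.132 with an estimated correlation). Centrosome genes had 10 higher and 0 lower of 12, median 0.54 (camera adjusted p = 0.000117, and adjusted p = 0.095 with an estimated correlation). The dREAM genes had 8 higher and 1 lower of 10, median 0.53 (camera adjusted p = 0.0152, and adjusted p = 0.583 with an estimated correlation). Immune genes were lower: 0 higher and 10 lower of 13, median -0.31 (camera adjusted p = 0.000973, and adjusted p = 0.0336 with an estimated correlation). In all 4133 probe sets differed, 2434 higher and 1699 lower, a share higher of 58.9% that was 47.6% after cyclic loess normalization.

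The RBFs were set against their binding partner E2F2. E2f2 was higher after RBFs than after E2F2 knockdown by 2.44 (8.76 ± 0.09 against 6.32 ± 0.21), vir-1 by 1.92 (7.98 ± 0.05 against 6.07 ± 0.19) and CG44325 by 1.49 (9.02 ± 0.09 against 7.53 ± 0.12). The matrix genes Pxn, Tig and Ppn differed by -2.37 (8.34 ± 0.10 against 10.71 ± 0.13), -2.31 (6.87 ± 0.11 against 9.18 ± 0.10) and -2.17 (8.95 ± 0.02 against 11.12 ± 0.07). Hemocyte genes were lower after RBFs knockdown, a call that held with an estimated correlation: 1 higher and 13 lower of 23, median -0.37 (camera adjusted p = 1.94e-07, and adjusted p = 0.0336 with an estimated correlation). The proteasome list was lower as well: 0 higher and 13 lower of 29, median -0.17 (camera adjusted p = 5.68e-05, or 0.762 with an estimated correlation). Oxidative phosphorylation genes had 2 higher and 12 lower of 54, median -0.09 (camera adjusted p = 0.044, or 0.901 with an estimated correlation). DNA replication genes had 7 higher and 1 lower of 48, median 0.06 (camera adjusted p = 0.0316, or 0.813 with an estimated correlation). Differing probe sets numbered 1941, 740 higher and 1201 lower, and 1234 without E2F2 replicate 3 or 1185 without RBFs replicate 3, and 3010 with array weights. The share higher was 38.1%, but 50.0% after quantile normalization and 26.2% after centring.

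Myb and E2F2 knockdown differed at 2522 probe sets, 1083 higher and 1439 lower after Myb knockdown, a share higher of 42.9% that was 53% after quantile normalization. Arpc3B was higher by 2.96 (8.83 ± 0.31 against 5.87 ± 0.11), E2f2 by 2.30 (8.61 ± 0.19 against 6.32 ± 0.21) and swa by 2.28 (6.80 ± 0.23 against 4.51 ± 0.11). Gr63a, vas and CG5250 differed by -3.42 (3.63 ± 0.13 against 7.06 ± 0.08), -2.98 (4.75 ± 0.13 against 7.72 ± 0.03) and -2.71 (5.58 ± 0.17 against 8.29 ± 0.08). Mitosis genes were lower after Myb knockdown: 1 higher and 21 lower of 39, median -0.23 (camera adjusted p = 9.87e-08, or 0.54 with an estimated correlation). The DNA replication list was higher: 23 higher and 2 lower of 48, median 0.17 (camera adjusted p = 6.72e-06, or 0.701 with an estimated correlation). Hemocyte genes were lower: 1 higher and 14 lower of 23, median -0.32 (camera adjusted p = 7.84e-05, or 0.0914 with an estimated correlation).

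L(3)MBT and E2F2 knockdown differed at 5104 probe sets, 2660 higher and 2444 lower after L(3)MBT knockdown; the share higher, 52.1%, was 63.1% after centring. RpS5b was higher by 3.30 (10.98 ± 0.05 against 7.67 ± 0.04), CG11052 by 3.05 (6.64 ± 0.10 against 3.59 ± 0.05) and the adhesion gene Nrg (neuroglian) by 2.58 (7.91 ± 0.07 against 5.33 ± 0.00). Gr63a, CG5250 and vas differed by -3.58 (3.48 ± 0.12 against 7.06 ± 0.08), -3.0 (5.29 ± 0.24 against 8.29 ± 0.08) and -2.36 (5.36 ± 0.06 against 7.72 ± 0.03). Oxidative phosphorylation genes were higher after L(3)MBT knockdown: 44 higher and 5 lower of 54, median 0.40 (camera adjusted p = 4.19e-07, and adjusted p = 0.762 with an estimated correlation). Higher too were ribosomal protein genes: 25 higher and 1 lower of 34, median 0.22 (camera adjusted p = 5.68e-05, or 0.701 with an estimated correlation). DNA replication genes had 28 higher and 2 lower of 48, median 0.22 (camera adjusted p = 0.00144, or 0.776 with an estimated correlation). Proteasome genes had 18 higher and 1 lower of 29, median 0.27 (camera adjusted p = 0.0103, or 0.813 with an estimated correlation). Mitosis genes had 24 higher and 2 lower of 39, median 0.19 (camera adjusted p = 0.0215, or 0.813 with an estimated correlation). Hemocyte genes were lower: 4 higher and 15 lower of 23, median -0.35 (camera adjusted p = 0.00726, or 0.337 with an estimated correlation). Also lower were fat body and gut genes: 0 higher and 11 lower of 17, median -0.26 (camera adjusted p = 0.00747, or 0.54 with an estimated correlation). Muscle genes had 1 higher and 9 lower of 12, median -0.25 (camera adjusted p = 0.0316, or 0.605 with an estimated correlation). Meiosis and testis genes had 2 higher and 8 lower of 12, median -0.40 (camera adjusted p = 0.0199, or 0.33 with an estimated correlation). The 18S signal of the L(3)MBT arrays applies here as well.

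Between Myb and Mip130 knockdown gNacalpha was higher after Myb knockdown by 1.14 (7.68 ± 0.59 against 6.54 ± 0.07), RpS5b by 1.08 (9.82 ± 0.08 against 8.74 ± 0.11) and vkg by 1.00 (8.83 ± 0.04 against 7.83 ± 0.06). CG5592, Pxt and Gr63a differed by -3.47 (4.63 ± 0.19 against 8.10 ± 0.11), -3.40 (7.0 ± 0.24 against 10.40 ± 0.07) and -3.08 (3.63 ± 0.13 against 6.71 ± 0.27). As a list DNA replication genes were higher after Myb knockdown: 17 higher and 2 lower of 48, median 0.15 (camera adjusted p = 5.12e-08, and adjusted p = 0.599 with an estimated correlation). Oxidative phosphorylation genes had 5 higher and 1 lower of 54, median 0.10 (camera adjusted p = 0.00588, and adjusted p = 0.813 with an estimated correlation). Germ line genes had 3 higher and 5 lower of 30, median -0.01 (camera adjusted p = 0.0406, and adjusted p = 0.701 with an estimated correlation). A total of 970 probe sets differed, 525 higher and 445 lower, a share higher of 54.1%. Without Myb replicate 3 the count was 1409 and the share 64.5%, and with array weights the count was 2243.

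Between the core subunits Mip120 and Mip130 183 probe sets differed, 104 higher and 79 lower after Mip120 knockdown. The proton pump subunit gene Vha55 was higher by 1.03 (9.20 ± 0.08 against 8.18 ± 0.07), Pxn by 0.93 (9.04 ± 0.11 against 8.11 ± 0.04) and CG14795 by 0.89 (7.85 ± 0.17 against 6.95 ± 0.07). Sdc, mip120 and the arginine kinase gene Argk1 differed by -1.51 (6.66 ± 0.10 against 8.17 ± 0.05), -1.12 (7.02 ± 0.18 against 8.14 ± 0.05) and -1.05 (8.05 ± 0.05 against 9.10 ± 0.05). Proteasome genes were lower as a list although no member was called alone: 0 higher and 0 lower of 29, median -0.10 (camera adjusted p = 4.89e-06, and adjusted p = 0.701 with an estimated correlation). DNA replication genes had 1 higher and 3 lower of 48, median -0.07 (camera adjusted p = 0.0391, or 0.813 with an estimated correlation). The count depended on the fit and on single arrays: it was 563 with the 6 arrays alone, 1024 with array weights, 110, 103 and 86 without Mip120 replicate 1, 2 and 3, and 77 and 76 without Mip130 replicate 2 and 3. The share higher, 56.8%, was 44.2% without Mip120 replicate 3.

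Calls after several knockdowns overlapped. Mip120 and Mip130 shared 313 probe sets higher and 323 lower, where 33.9 and 49.2 would be shared by independent lists, a value that ignores the shared controls, and 5 went opposite ways. Lin-52 and RBFs shared 418 higher (independent 78.0) and 482 lower (98.9). Mip40 and Mip130 shared 223 higher (independent 27.3) and 234 lower (41.6), and E2F2 and RBFs 543 higher (146) and 206 lower (84.5). Myb and E2F2 shared 34 higher (independent 30.1) and 12 lower (24.4), while 142 went opposite ways (60.5). With each other knockdown L(3)MBT shared more higher probe sets than independent lists, and with each but E2F2 fewer lower. With Mip120 these were 513 (independent 263) and 205 (284), and with E2F1 1127 (693) and 744 (844). Across probe sets, which are not independent replicates, the changes after Mip120 and Mip130 knockdown had r = 0.86 and a covariance of 0.0403, where simulated unchanged groups gave r = 0.50 and a covariance of 0.00297. For Lin-52 and RBFs r was 0.69, for Mip40 and Mip130 0.65, for E2F2 and RBFs 0.52, and for Myb and E2F2 -0.11, with covariances 0.0279, 0.0245, 0.0214 and -0.0065 above the simulated values. Of the 36 pairs, with r from -0.11 to 0.86, these are 5.

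All of the knockdowns of Mip40, Mip120, Mip130, Lin-52, E2F2 and RBFs raised 63 probe sets. Among them was vas, with rises of at least 1.55 to 3.00 apart from Mip40, where both means lay in the background range. Knockdowns of Mip40, Mip120, Mip130, Lin-52 and Myb all lowered 51 probe sets, Pxn and Klp61F among them. E2F1 knockdown lowered both more (-2.62 and -1.30). The second count was 27, 25 and 83 without control replicate 1, 2 and 3.

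**Figure D5:**
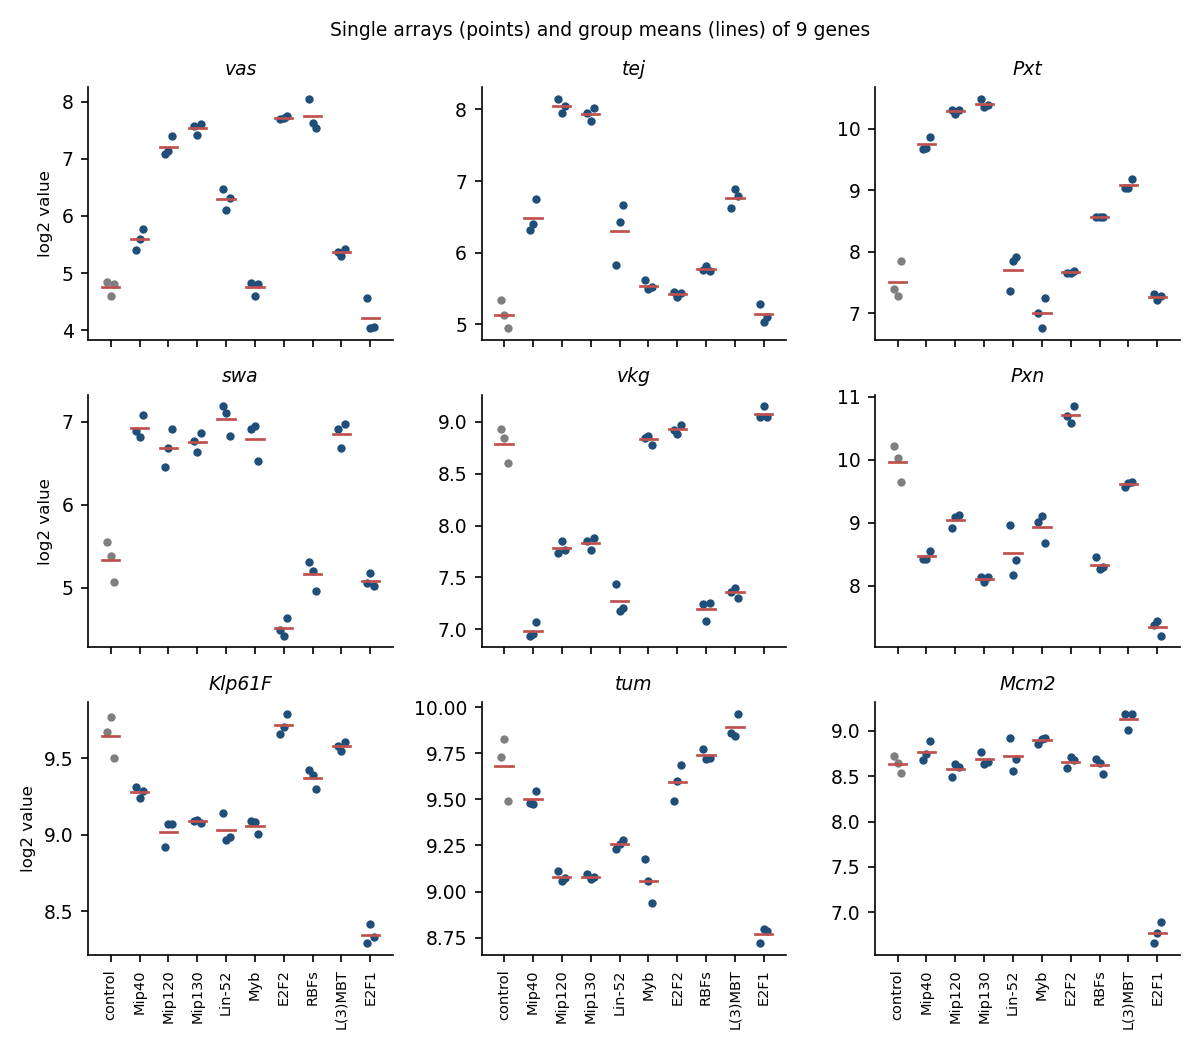
Signal (log2) of selected genes on each of the 30 arrays by group; points are arrays and bars are means (n = 3). The germ line helicase gene vas was at 4.75 in control and 7.75 after RBFs knockdown, and Mcm2 at 8.64 in control and 6.77 after E2F1 knockdown.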

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

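Chosen only after the results were seen were the comparison of control probe sets, the level classes, the loess count, the test of foreign control probe sets, the test of the 18S signal and all tests of the collagen genes; the lists' tests against signal level and the permutation of arrays were set out before their results. The control probe sets, which no comparison uses, gave signals at least 1 above the control arrays in L(3)MBT and E2F1 knockdown. In L(3)MBT knockdown the 18S ribosomal RNA probe sets were above control by 2.65 (3 prime), 4.64 (5 prime) and 5.45 (middle). The GAPDH probe sets were above control by 1.00 (3 prime) and 1.07 (5 prime) in L(3)MBT knockdown, and by 1.13 (3 prime) and 1.10 (5 prime) in E2F1 knockdown.

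After L(3)MBT knockdown the median change of tested genes was above 0 in the brightest 4 of 10 classes by control level, below 0 in the second to the sixth, and 0.09 in the dimmest. Over all probe sets, without the filter, it was -0.13 in the dimmest and 0.19 in the brightest class. A wider intensity scale on these arrays may explain lower dim signals: the foreign control probe sets, with no target in flies, had a median of -0.28, and 18 of 23 lay below every control array. It is argued against as the whole cause of the many calls, since cyclic loess normalization, which removes such a trend, left 5486 changed probe sets. Against 10000 random lists matched for signal level, the lists of mitosis (percentile 99.82), oxidative phosphorylation (99.99), muscle (1.95) and fat body and gut genes (0) lay outside the central 95%, while DNA replication (96.76) and ribosomal proteins (73.81) lay inside, so signal level could account for these last ones. It may also explain part of oxidative phosphorylation, whose median fell from 0.40 to 0.17 with cyclic loess and 0.10 with quantile normalization, which ended its call (adjusted p 0.108 and 0.115, range 7.54e-05 to 0.722). A separate RNA preparation or labelling cannot be told apart from the knockdown, since the 18S signal (5.45 for the middle probe set) is shared by all 3 arrays of the group and no batch is given; an effect of L(3)MBT itself stays open too.

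The collagen genes vkg and Col4a1, picked after their values were seen, were lower after Mip40, Mip120, Mip130, Lin-52, RBFs and L(3)MBT knockdown. A smaller share of hemocyte-like cells, which would lower hemocyte genes alike, stays open. The 21 other hemocyte genes (2 to 9 rose, 4 to 8 fell) had a median at least 1.86 of their SD above both collagens. Picking the collagens by value made that likely. RNA degradation from the 5 prime end is argued against by the control genes. Their lowest 5 prime minus 3 prime signal against control was -0.21 in the first 5 of these and -0.36 after L(3)MBT (actin, with GAPDH 0.07, eIF-4a 0.06). There the middle signals fell more (actin -0.81, eIF-4a -0.72, GAPDH -0.24), which that loss does not explain. An effect of the knockdowns stays open, untested.

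The proteasome and oxidative phosphorylation lists were lower in several knockdowns. Swings of single arrays were tested by permuting 27 arrays (9 groups, L(3)MBT left out) 100000 times: for the proteasome list the permutation p was 0.00078, which argues against them, and for oxidative phosphorylation it was 0.0512, which leaves them open. A swing shared by the 3 arrays of a group was not excluded. The signal level of the proteasome probe sets is argued against, since the list's percentile among level-matched lists was 0 (Mip120), 0.06 (Mip130), 0 (Lin-52) and 0 (RBFs). An effect of the knockdowns stays open, and the lists lost their calls with an estimated correlation.

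The 6 arrays of a contrast allow 10 splits, too few for a share under 0.05. In each of the 15 contrasts 1 split, the real one, gave as many changed probe sets, and the highest other split gave 1 (Mip40, against 1240), 0 (Mip120, 1498), 11 (Mip130, 857), 517 (Lin-52, 1513), 82 (Myb, 451), 0 (E2F2, 1987), 2 (RBFs, 1819), 0 (L(3)MBT, 5723) and 0 (E2F1, 4226). Among direct contrasts the highest other was 87 for Myb and Mip130 (real 970) and 0 for E2F2 and E2F1 (4133), RBFs and E2F2 (1941), Myb and E2F2 (2522), L(3)MBT and E2F2 (5104) and Mip120 and Mip130 (183). The split with 517 set Lin-52 replicate 1 with control replicates 1 and 2 against the rest. For called lists, the splits with as many as the real one, the real count and the highest other were 3, 5 and 9 (Mip40), 7, 4 and 5 (Mip120), 2, 5 and 5 (Mip130), 1, 6 and 4 (Lin-52), 8, 3 and 6 (Myb), 8, 3 and 6 (E2F2), 4, 4 and 5 (RBFs), 6, 6 and 11 (L(3)MBT) and 8, 6 and 8 (E2F1).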

How the results depend on the processing

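Of the alternatives below, cyclic loess, the fit without L(3)MBT and the block within 6 arrays were chosen after the results were seen. No count of changed probe sets moved by over 1.5 times with quantile normalization, centring, cyclic loess, no intensity trend, 1 probe set per gene, the replicate block or without the L(3)MBT arrays. Without a filter, which tests more probe sets, L(3)MBT gave 9542 and L(3)MBT against E2F2 7953; at the 70th percentile, which tests fewer, L(3)MBT gave 3745. Array weights gave 2515 (Mip40), 2674 (Mip120), 1955 (Mip130), 2302 (Lin-52), 766 (Myb), 3010 (RBFs against E2F2), 2243 (Myb against Mip130), 1024 (Mip120 against Mip130), and 119 higher in the 6 and 118 lower in the 5 knockdowns counted together; the cause was not tested. With an absolute change of at least 1, a stricter rule, the counts were 43, 54, 50, 34, 23, 23, 35, 213 and 305 (Mip40, Mip120, Mip130, Lin-52, Myb, E2F2, RBFs, L(3)MBT, E2F1), 262 (E2F2 against E2F1), 32 (RBFs against E2F2), 86 (Myb against E2F2), 150 (L(3)MBT against E2F2), 48 (Myb against Mip130), 5 (Mip120 against Mip130), and 0 and 0 for the joint counts. The 6 arrays alone, fewer samples for the spread, gave 639 (Lin-52), 200 (Myb), 563 (Mip120 against Mip130), and 40 and 25 for the joint counts. Leaving out each replicate gave 566 to 1169 (Mip130), 76 to 150 (Mip120 against Mip130), 1185 to 1954 (RBFs against E2F2) and 25 to 83 (joint lower); the others stayed within 1.5 times. All 42 list calls were lost with an estimated correlation; quantile normalization called 45 lists (39 shared with the 42), cyclic loess 46 (39 shared), array weights 45 (38 shared), centring 42 (42 shared) and the replicate block 42 (42 shared). The ribosomal list after L(3)MBT knockdown lost its call with cyclic loess (median -0.045, near 0; the cause was not tested). Of the named genes none reversed; calls lost numbered 6 with quantile normalization, 11 with centring, 7 with cyclic loess, 6 with array weights, 5 without a filter, 26 with the 6 arrays alone and 328 with an absolute change of at least 1, and 188 over all left-out replicates, where 2722 held. Signal near background limits what can be seen: Rbf, at 4.92 in control, was below the filter.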

Other observations

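Genes named in this part, and all neighbour tests but those of the E2F2 set and the joint set, were chosen only after the results were seen. Among the probe sets higher in all of the Mip40, Mip120, Mip130, Lin-52, E2F2 and RBFs knockdowns were both subunits of ferritin, the iron storage protein. Fer2LCH changed by 0.88, 0.55, 0.41, 0.66, 0.68 and 0.90 in that order, and Fer1HCH by 0.78, 0.30, 0.33, 0.47, 0.22 and 0.59. These rises were not particular to the 6 knockdowns. Both genes changed more after E2F1 knockdown (1.32 and 1.15), and by 1.13 and 0.75 after L(3)MBT knockdown. After Myb knockdown they changed by -0.001 and -0.086.

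Lower in all of the Mip40, Mip120, Mip130, Lin-52 and Myb knockdowns were the augmin subunit genes msd1 (-0.89 to -0.30) and msd5 (-0.88 to -0.27) of chromosome segregation. E2F1 knockdown lowered both more (-1.35 and -1.10). No enrichment was tested for any of these.

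It was asked whether genes that rose after E2F2 knockdown lie next to each other in the genome more often than random sets of tested genes. The 1012 genes formed 126 adjacent pairs where random sets averaged 90.4 (one-sided permutation p = 0.0001, the smallest that 10000 sets can give), so neighbouring genes may have risen together. This was not particular to E2F2: of 19 sets tested 15 had an adjusted p under the threshold, genes that fell included, such as those lower after Mip130 knockdown (33 pairs where random sets averaged 14.7). The genes higher in all of the 6 knockdowns above formed 1 pair where random sets averaged 0.203 (one-sided permutation p = 0.186), so no excess was detected there. Probe sets that read overlapping neighbouring transcripts were not tested as a cause.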
